A study of Homo sapiens with 6 samples.

How the data were processed

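RNA-seq libraries were made from NCI-H1975, a human lung adenocarcinoma cell line, and from its derivative H1975/OSI, which had been selected for resistance to osimertinib, an inhibitor of the epidermal growth factor receptor kinase. Per the labels, 3 libraries came from the resistant line and 3 from control NCI-H1975. The labels name total RNA and a pair of commercial library kits, NEBNext Ultra and SMARTer. Strand handling, sequencing machine and culture conditions at harvest were not given in the sources used here. The sample titles call the resistant libraries Drug and the others Control. They do not say whether this means the selection or drug present at harvest. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

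The authors deposited a table per library with 30330 Ensembl genes, gene coordinates, biotype, transcription factor family and a value on a signal scale. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool and the normalization tool were not given in the sources used here. Within each library, 100% of the deposited signal values were whole multiples of a single number within 0.001 reads, with a largest distance from a whole read of 5.27e-05. The values are therefore read counts per gene divided by 1 size factor per library, and they are called normalized read counts below. Whole reads were recovered by dividing each library by its own step. Recovered totals ranged from 15174126 to 16588479 reads per library. A floor of 3 reads per library was used for genes without reads, and intervals on ratios of reads cover counting error only, at a confidence level of 95%.

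Because the deposited values were normalized and not raw, the branch of the design written for normalized values was used as the main test, and the count tests were added as alternatives on the recovered reads. Values were transformed as log2(value + 1). Genes at 1 or more in at least 3 libraries were kept, which left 24560. Group differences were tested with limma-trend (limma 3.58.1 in R 4.3.3, robust empirical Bayes, group as the sole term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates the change of genes with few reads. An absolute log2 fold change of 1 defined a 2-fold change. With 3 libraries against 3, an exact permutation test of a single gene cannot go below 0.1, so none was used for single genes.

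A set of 40 gene lists was fixed before the data were examined. Each was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. Chromosomal windows of 50 adjacent tested genes were tested with camera at the preset correlation. Gene symbols came from a table of Ensembl identifiers, which gave a symbol for 23695 of the 30330 genes. Genes were named by a rule fixed before the data were examined. It took the 8 protein-coding genes with the largest rise and the 8 with the largest fall, among genes past the threshold with non-overlapping groups and at least 5 counts per 1e6 reads in the higher group. It also took the 3 members with the smallest adjusted p in the direction of each called list, and a fixed set of 21 genes linked to EGFR inhibitor resistance. The rule gave 98 genes, of which some are not named below. ABCB1 was in that fixed set but was not among the tested genes, so no result is given for it. A further 103 genes that were checked against every setting fall outside the rule and were chosen after their values were seen; each is either a member of a list direction with 5 or fewer called members or a gene singled out below.

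Replicate numbers are shared between the groups, and nothing in the labels ties a number to a day or batch. The check of this is given with the other settings. Alternatives fixed in advance were quantile normalization, median centring, no filter, a minimum of 5, pseudocounts of 0.1 and 0.01, limma without trend, the replicate number as a block, each library left out in turn, windows of 100 and 25 genes, and the other set tests. Alternatives added after the data had been seen were edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom on the recovered reads, removal of each library's trend on GC content and gene length, the lists without genes of the lower chromosomal windows, and the windows with an estimated correlation and with fry. GC content came from GENCODE 29 transcripts and was available for 24548 of the 24560 genes.

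The pipeline was tested on simulated data for 3 resistant against 3 control libraries, in which 25205 genes were tested. limma-trend called 92 of 100 genes changed 2-fold and 61 of 100 genes changed 1.5-fold. It also called 13 unchanged genes, so that 7.83% of its calls were false, above the nominal level in this single run. Genes were simulated independently and with the same dispersion for all, so these shares need not hold for the real libraries. edgeR called 94 of the 2-fold genes and 8 unchanged genes. All 4 windows inside a simulated lowered block were called, and 0 of 495 windows outside it. Overlapping genes on either strand can share reads because strand handling was not stated; the overlaps with the most reads are named beside the genes concerned.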

Results

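The series compared NCI-H1975 cells, a lung adenocarcinoma line, with a derivative that had acquired resistance to osimertinib. The derivative, H1975/OSI, was obtained by exposure to 0.03, 0.1, 0.3, 1 and 3 µM osimertinib over 7 months, per the labels. The question was which transcripts differ between the resistant line and its control. There were 3 resistant and 3 control libraries, with 15174126 to 16276518 recovered reads in the resistant group and 15813497 to 16588479 in the control group. The minority members named within lists, EGR1 and the tests on recovered reads were chosen after values had been seen. All values below are normalized read counts, as mean ± SD (n = 3 per group), unless stated otherwise. Coordinates are on GRCh38. Resistant library 1 stood apart from the other resistant libraries: the chi-square per gene was 12.1 and 13.5 against resistant 2 and 3, and 2.42 between resistant 2 and 3. Among control libraries it ranged from 2.55 to 3.93. No pair of libraries differed by less than sampling noise. The mitochondrial share of reads was 5.53 ± 0.178% (SD, n = 3) in resistant and 6.88 ± 0.440% (SD, n = 3) in control libraries. The protein-coding share was also lower in resistant libraries, at 96.09 ± 0.114% against 96.72 ± 0.109% (SD, n = 3). Whether this difference in composition contributes to the fold changes was not tested.

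The resistant line expressed lower levels of MAPK output, cell cycle and epithelial genes, and of the ERBB receptor and ligand list on balance. It expressed higher levels of mesenchymal, hypoxia and stress response genes. Of these lists, MAPK output and G2/M kept their calls with an estimated correlation, while the others did not: adjusted p = 0.147 with an estimated correlation for the ERBB, G1/S and epithelial lists, 0.311 for mesenchymal and stress response genes and 0.355 for hypoxia targets. COL1A2, a collagen I chain, rose from 698 ± 62.5 to 29275 ± 1411 normalized read counts. EPCAM, an epithelial adhesion molecule, fell from 379 ± 21.9 to 17.6 ± 2.03. EGFR itself was at 4988 ± 739 in resistant and 5487 ± 401 in control libraries, a difference that did not pass the test (log2 fold change -0.14, limma adjusted p = 0.205). Of 24560 genes tested, 10204 passed the threshold, 5010 higher and 5194 lower in the resistant line. A 2-fold change was reached by 1930 higher and 1404 lower genes, and a 4-fold change by 561 and 380. The groups did not overlap for 50.1% of genes, against 10% expected by chance. Median centring of each library moved the median of all genes by -0.13 and the share of calls that were higher from 49.1% to 35.8%. It also turned the balance of 2-fold changes to 1560 higher and 1863 lower, so the balance between rises and falls depends on the scaling.

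Genes of the ERBB receptor and ligand list fell on balance, while EGFR did not pass the test. The list as fixed also holds ERRFI1 and LRIG1, which are neither ERBB receptors nor ligands. Of 14 tested members of the ERBB list, 8 fell and 2 rose (9 fell when adjusted over the list alone), with a median log2 fold change of -0.58 and a camera adjusted p of 0.00279 (adjusted p = 0.147 with an estimated correlation). AREG, the amphiregulin ligand, fell from 235 ± 10.5 to 19.5 ± 9.45 (log2 fold change -3.65 ± 0.30 SE, adjusted p = 3.36e-07). NRG1, a ligand of ERBB3, fell by 1.27 and HBEGF, another EGFR ligand, by 0.74 on the log2 scale. The members that rose were EGF (log2 fold change 1.64) and EPGN (1.54), and EPGN lost its call without resistant 1 or 3 or without control 1 or 2. ERBB3 fell by 1.04, with 40.5 ± 7.08 against 83.7 ± 10.8. ERBB2, which overlaps MIEN1, was lower by a smaller amount (log2 fold change -0.25, adjusted p = 0.0142), a call lost without control 1 (-0.23) or control 2 (-0.19), with quantile normalization (-0.18) and with limma without trend (adjusted p = 0.187). EGFR lies on chromosome 7 from 55019021 to 55211628 (ENSG00000146648), and the 95% interval of its log2 fold change ran from -0.33 to 0.04. Without resistant 1 the log2 fold change of EGFR was -0.26 (adjusted p = 5.62e-05), and with median centring it was -0.28 (adjusted p = 0.008).

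**Figure D1:**
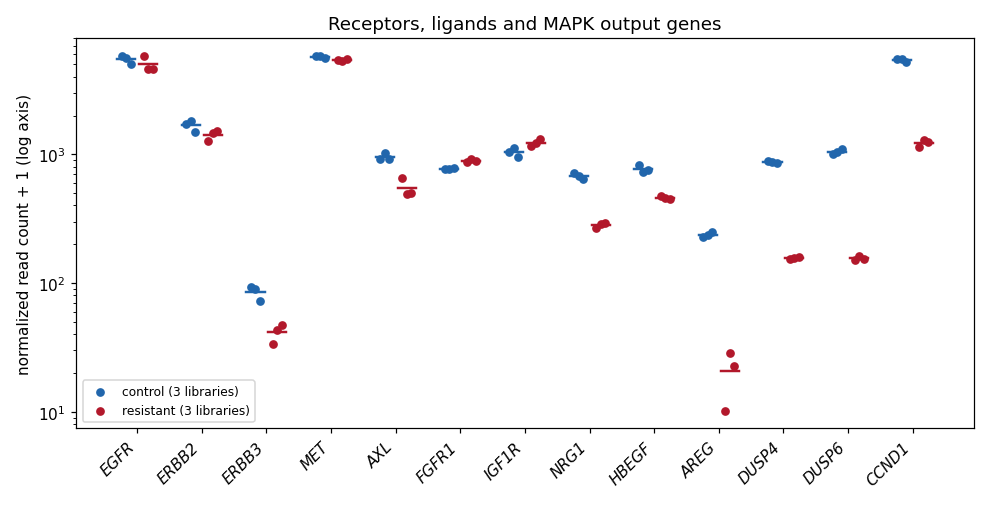
Normalized read counts plus 1 on a log axis for receptors, ligands and MAPK output genes; each point is a library (blue, control; red, resistant) and each bar is the mean of 3 libraries. EGFR and MET overlap or nearly overlap between groups, whereas AREG, DUSP4, DUSP6 and CCND1 are lower in every resistant library.

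Receptors that can act beside EGFR moved in different directions. MET, the hepatocyte growth factor receptor, was at 5399 ± 72.7 and 5723 ± 140 and did not pass the test (log2 fold change -0.08, 95% interval -0.21 to 0.04, adjusted p = 0.278); its sign turned to 0.05 with quantile normalization, and with median centring it was called at -0.22. AXL, a receptor of GAS6, fell from 955 ± 58.2 to 547 ± 92.9. FGFR1 (log2 fold change 0.21, overlapping LETM2) and IGF1R (0.25) were called higher by small amounts. These calls ended with median centring, at 0.08 and 0.11, and also with limma without trend. The FGFR1 call was also lost with GC content and gene length removed (0.15) and without resistant 2 (0.19), control 1 (0.20) or control 2 (0.21), and the IGF1R call without resistant 3 (0.20) or control 3 (0.18). The list of other receptor tyrosine kinases and their ligands was not called, with 12 members higher and 7 lower of 28 (median 0.25, adjusted p = 0.329).

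MAPK output genes, which are transcribed when ERK is active, fell as a group. Of 18 members, 15 fell and 1 rose, with a median log2 fold change of -0.92 (camera adjusted p = 9.43e-10; adjusted p = 0.0426 with an estimated correlation). The median was -0.48 over the 13 members outside the lower chromosomal windows described below. DUSP6, a phosphatase that inactivates ERK (chromosome 12, 89347232 to 89353271, ENSG00000139318), fell from 1045 ± 51.6 to 154 ± 5.32 (log2 fold change -2.75 ± 0.09 SE, adjusted p = 6.84e-17). DUSP4 fell from 872 ± 15.7 to 156 ± 2.46, and CCND1, which encodes cyclin D1 and overlaps LTO1, from 5404 ± 133 to 1225 ± 76.8. EGR1, an immediate early transcription factor singled out after its value was seen, fell by 4.39. SPRY1, a feedback inhibitor, was the member that rose (0.90).

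Cell cycle genes fell without exception among those tested. All 23 G1/S genes and all 22 G2/M genes passed the threshold as lower, with medians of -0.82 and -0.92. The camera adjusted p was 2.66e-15 for G1/S and 2.00e-17 for G2/M, and with an estimated correlation the adjusted p was 0.147 for G1/S and 0.0365 for G2/M. RRM2, a subunit of ribonucleotide reductase, fell from 1915 ± 83.1 to 472 ± 28.3. MCM4, part of the replicative helicase, fell by 1.58 and UHRF1, a maintenance methylation factor, by 1.39 on the log2 scale. MKI67, a proliferation marker, fell from 7908 ± 648 to 2302 ± 238. CCNB1, TOP2A and AURKA, mitotic genes, had log2 fold changes of -1.49, -1.09 and -1.22. Replication-dependent histones, a list fixed as a sign of RNA quality, also fell for 7 of 12 members (median -0.53, adjusted p = 0.0126; adjusted p = 0.197 with an estimated correlation), among them H2BC5, H2BC21 and H1-2.

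Epithelial genes fell and mesenchymal genes rose, while VIM did not pass the test. Of 26 epithelial genes, 20 fell and 1, ELF3, rose (median -0.85, adjusted p = 1.62e-08; adjusted p = 0.147 with an estimated correlation). The median was -0.80 when 3 members with 3 or fewer reads in a group were set to the floor. CDH1, which encodes E-cadherin, fell from 368 ± 39.2 to 116 ± 16.5, and ST14 and LAMA3 fell by 2.78 and 1.62. EPCAM lies on chromosome 2 from 47345158 to 47387601 (ENSG00000119888). Of 23 mesenchymal genes, 14 rose and 2, TNC and CDH11, fell (median 0.68, adjusted p = 4.14e-06; adjusted p = 0.311 with an estimated correlation). TAGLN rose from 916 ± 28.6 to 3222 ± 134, although it overlaps PCSK7. ACTA2, the smooth muscle actin, rose from 47.9 ± 6.03 to 373 ± 29.2 and overlaps FAS. VIM was at 23212 ± 3336 and 25766 ± 1194 (log2 fold change -0.16, 95% interval -0.32 to 0.01, adjusted p = 0.12). Without resistant 1, VIM was called lower (-0.27, adjusted p = 4.36e-07), as it was with quantile normalization (-0.25) and median centring (-0.29).

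Genes of the TGF-beta pathway and YAP/TAZ targets rose on balance. In the TGF-beta list, 11 of 17 members rose and 4 fell (median 0.41, adjusted p = 0.00249; adjusted p = 0.147 with an estimated correlation), with a median of 0.71 over the 15 members outside the lower chromosomal windows. INHBA, the activin A subunit, rose from 80.4 ± 12.7 to 1674 ± 130, TGFB2 from 700 ± 19.4 to 2548 ± 88.3, and BAMBI from 670 ± 29.8 to 2129 ± 192. The members that fell were LTBP1, BMP4, TGFB1 and TGFBR2. In the YAP/TAZ list, 10 of 21 rose and 5 fell (11 rose when adjusted over the list alone; median 0.29, adjusted p = 0.0174; adjusted p = 0.573 with an estimated correlation). CCDC80 and GADD45B rose by log2 fold changes of 1.30 and 1.23, and the members that fell were NT5E, MYOF, AXL, DOCK5 and FJX1, of which DOCK5 and FJX1 lost their calls without single libraries. Resistant 1 stood higher on this list, with a mean log2 difference from control of 0.53 against 0.24 and 0.29, and the call was lost without it (0.17, adjusted p = 0.0612). YAP1 itself rose from 2376 ± 112 to 3054 ± 167. Squamous genes fell for 7 of 11 members, and KRT16 and KRT17 rose (median -1.99, adjusted p = 0.00884; adjusted p = 0.171 with an estimated correlation). SERPINB4 and SERPINB3, near-identical paralogs whose reads can be split between them, had log2 fold changes of -3.57 and -2.30, and TP63, a basal cell transcription factor, of -1.99. With 3 members at the floor the squamous median was -1.28, and the call was lost without control 1 (-1.45, adjusted p = 0.0609) or control 3 (-1.32, adjusted p = 0.0817), with edgeR (adjusted p = 0.117) and with limma-voom (adjusted p = 0.118).

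Hypoxia targets and genes of the integrated stress response rose. Of 19 hypoxia targets, 13 rose and 1, BNIP3, fell (14 rose when adjusted over the list alone; median 0.71, adjusted p = 2.52e-07; adjusted p = 0.355 with an estimated correlation). ANGPTL4, a secreted lipase inhibitor, rose from 2710 ± 149 to 13351 ± 2142, P4HA1 from 2351 ± 50.7 to 5129 ± 530, and EGLN1 by a log2 fold change of 0.58. Of 22 integrated stress response genes, 14 rose and 0 fell (median 0.45, adjusted p = 1.09e-07; adjusted p = 0.311 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 1016 ± 37.2 to 5384 ± 725, NUPR1 from 219 ± 19.0 to 917 ± 136, and PHGDH, the entry enzyme of serine synthesis, from 1045 ± 27.9 to 2475 ± 112. Resistant 1 stood higher on both lists: its mean log2 difference from control was 1.05 for hypoxia targets, against 0.57 and 0.58, and 0.97 for the stress response, against 0.66 and 0.62.

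NF-kB and inflammatory cytokine genes rose on balance and interferon-stimulated genes fell. In the NF-kB list, 16 of 26 members rose and 6 fell (median 0.34, adjusted p = 0.00311; adjusted p = 0.311 with an estimated correlation). The mean over all members was smaller, at 0.10, and resistant 1 lay the other way, with a mean log2 difference from control of -0.04 against 0.19 and 0.14. SAA1, an acute-phase protein, rose from 1209 ± 93.0 to 3714 ± 279, and the chemokines CXCL3 and CXCL2 rose by 1.81 and 1.18. Of 26 interferon-stimulated genes, 17 fell and 5 rose (median -0.48, adjusted p = 0.00156; adjusted p = 0.311 with an estimated correlation). ISG15, a ubiquitin-like protein, fell from 3889 ± 101 to 1813 ± 80.5, OAS3 by 1.09, and IFIT1, which overlaps LIPA, by 1.39. The members that rose were STAT2, XAF1, IFI44L, CXCL10 and IRF9, and IRF9 lost its call without resistant 2 (0.47) or control 2 (0.46).

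Genes of mitochondrial respiration fell in both genomes. Of 28 nuclear OXPHOS subunits, 25 fell and 0 rose (median -0.46, adjusted p = 1.81e-09; adjusted p = 0.25 with an estimated correlation). ATP5F1B, the catalytic beta subunit of ATP synthase, fell from 16914 ± 70.0 to 9090 ± 192, and ATP5MC1 and UQCRQ by 1.36 and 0.80. The 22 OXPHOS genes outside the lower chromosomal windows described below had a median of -0.40. Of 13 mitochondrially encoded mRNAs, a list fixed as a sign of RNA quality, 11 fell (median -0.67, adjusted p = 4.14e-06; adjusted p = 0.311 with an estimated correlation), alongside the lower mitochondrial share of reads given above. MT-CO3, which overlaps MT-ATP6, fell by 1.24, MT-ND3 by 1.07 and MT-ND1 by 0.78.

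Lipid synthesis, heat shock and NRF2 target genes fell. Cholesterol synthesis genes fell for 12 of 23 members and rose for SC5D (2 rose when adjusted over the list alone; median -0.30, adjusted p = 0.00536; adjusted p = 0.476 with an estimated correlation), with EBP, a sterol isomerase, lower by a log2 fold change of -0.56. Fatty acid synthesis genes fell for 9 of 13 and rose for ACSL1 (2 rose when adjusted over the list alone; median -0.45, adjusted p = 0.00169; adjusted p = 0.147 with an estimated correlation). The fatty acid median was -0.30 over the 9 members outside the lower chromosomal windows. ELOVL6, ACLY and FADS1, which overlaps FADS2, fell by 0.81, 0.69 and 0.59. Heat shock proteins fell for 8 of 12 and rose for HSPB1 (median -0.58, adjusted p = 0.000672; adjusted p = 0.147 with an estimated correlation). HSPD1, which overlaps HSPE1, fell from 10748 ± 373 to 5640 ± 152, HSP90AA1 by 0.87 and HSP90AB1 by 0.70. NRF2 targets fell for 14 of 26 and rose for SLC7A11, OSGIN1 and PIR (median -0.25, adjusted p = 0.0115; adjusted p = 0.311 with an estimated correlation), with ABCC3 and UGDH lower by -0.98 and -0.71. The PIR call was lost without resistant 2 or 3 or without control 1 or 2.

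Among BCL2 family genes, 7 of 15 fell and 2, BID and BAD, rose (median -0.19, adjusted p = 0.0277; adjusted p = 0.216 with an estimated correlation). BCL2L11, which encodes the pro-apoptotic BIM and overlaps MIR4435-2HG, fell from 620 ± 63.7 to 297 ± 50.3. PMAIP1, the pro-apoptotic NOXA, fell by 0.81, and the anti-apoptotic BCL2L1 and MCL1 by 0.59 and 0.46. The call was lost with edgeR on the recovered reads (adjusted p = 0.0878), with limma-voom on them (adjusted p = 0.0914), with quantile normalization and with a minimum of 5. BAD lost its call without resistant 2 (0.28) or control 3 (0.25). ER chaperones were at the edge of the threshold, with 6 of 16 lower and 2, EDEM1 and SEL1L, higher (median -0.14, adjusted p = 0.0496; adjusted p = 0.585 with an estimated correlation). CANX, PDIA6 and SDF2L1 fell by 0.80, 0.79 and 0.77. The ER chaperone call was lost with edgeR (adjusted p = 0.148), with quantile normalization and without resistant 2 (-0.15), resistant 3 (-0.16), control 1 (-0.15) or control 2 (-0.13). It also ended with the replicate block (camera adjusted p = 0.0527) and without genes of the lower chromosomal windows (camera adjusted p = 0.159). Other settings that ended it were limma-voom, a minimum of 5, a pseudocount of 0.01 and removal of GC and length trends.

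**Figure D2:**
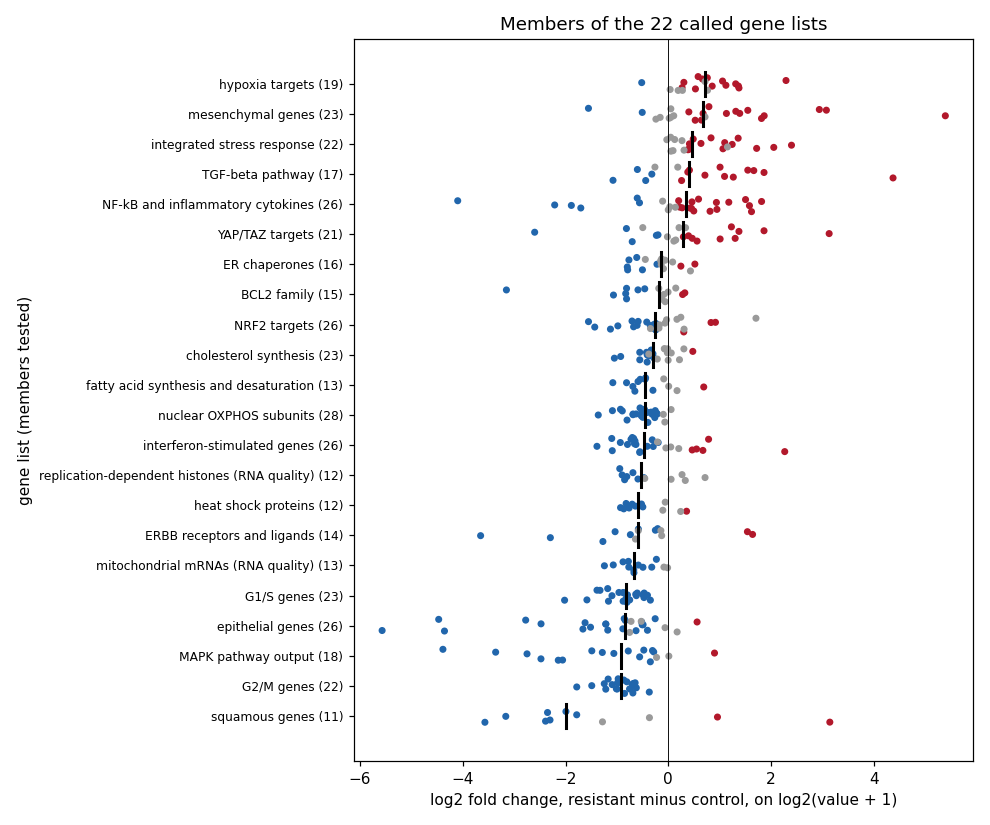
Log2 fold change, resistant minus control, of each tested member of the 22 called gene lists; points are genes (red, higher; blue, lower; grey, not past the threshold), vertical bars are medians and the number tested stands in parentheses. All G1/S and G2/M members lie below 0, while hypoxia and mesenchymal medians lie at 0.71 and 0.68.

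Members of the RAS and PI3K pathways changed by small amounts. BRAF (log2 fold change 0.48, overlapping NDUFB2) and PIK3CA (0.34, overlapping KCNMB3) were higher, and NRAS was lower (-0.24). The PIK3CA call ended with median centring (0.20) and the NRAS call without control 3 (-0.20), and both ended with limma without trend, at adjusted p = 0.0519 and 0.105. ABCG2, a drug efflux transporter, fell from 182 ± 11.7 to 54.8 ± 16.2. The list of ABC drug transporters was not called (median -0.06, adjusted p = 0.613), with ABCC2, ABCC3 and ABCG2 lower and ABCC1 and ABCC6 higher of 10 tested.

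The largest rises and falls were in single genes of varied function. OR2T8, an olfactory receptor gene whose family members are close paralogs, had 364 reads in the resistant and 0 in the control libraries and was at least 39.3-fold higher against a floor of 3 reads per library. COL1A2 lies on chromosome 7 from 94394561 to 94431232 (ENSG00000164692) and rose by a log2 fold change of 5.39 ± 0.07 SE (adjusted p = 4.94e-25). DUSP15, PPP4R4, NGFR, OLR1, GSTA2 and TMEM47 rose by log2 fold changes of 5.56, 5.48, 5.39, 5.37, 5.01 and 5.01. OLR1 overlaps TMEM52B, and GSTA2 has the paralog GSTA1. The matrix metalloproteinases MMP1, MMP13 and MMP3, neighbours on chromosome 11, fell from 770, 704 and 295 control reads to 2, 3 and 2 resistant reads. The ratio of reads scaled by the library size factors, control over resistant, was 398 for MMP1 (95% interval 110 to 3296), 243 for MMP13 (82.8 to 1180) and 153 for MMP3 (41.9 to 1266). ESRP1, an epithelial splicing regulator, had 3 resistant and 252 control reads, a scaled ratio of 86.9 (29.4 to 424). FOXJ1, PXDN, RGS4 and MYEOV had log2 fold changes of -5.49, -5.46, -4.98 and -4.85.

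**Figure D3:**
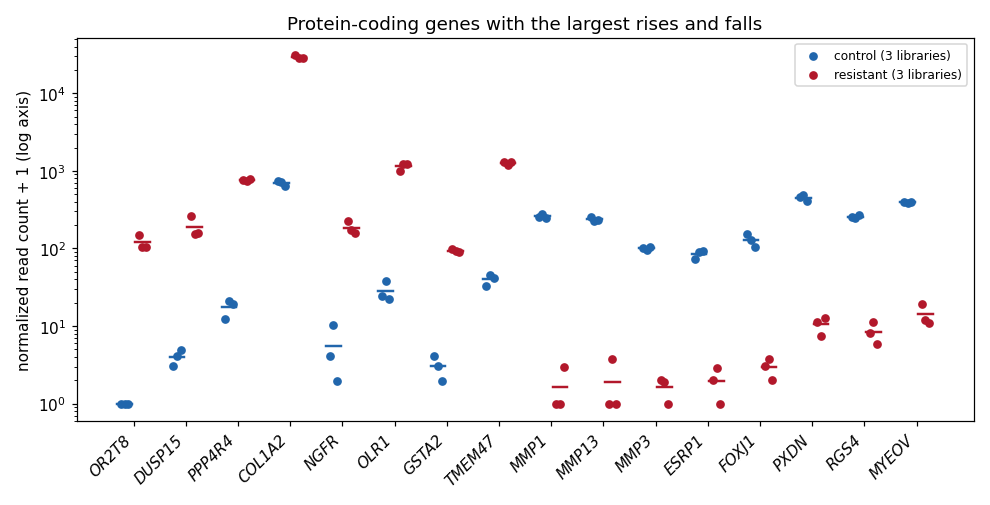
Normalized read counts plus 1 on a log axis for the 8 protein-coding genes with the largest rise and the 8 with the largest fall; each point is a library (blue, control; red, resistant) and each bar is the mean of 3 libraries. The rule that picked the 16 genes required groups that do not overlap. COL1A2 reaches 29275 in the resistant line.

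The remaining lists did not pass camera. Among pathways, Wnt genes had 5 members higher and 6 lower of 16 (adjusted p = 0.629), Notch genes 5 and 3 of 13 (adjusted p = 0.647), p53 targets 3 and 2 of 16 (2 and 2 adjusted over the list alone; adjusted p = 0.526) and drug-metabolising enzymes 2 and 3 of 18 (adjusted p = 0.844). Antigen presentation genes had 8 higher and 9 lower of 20 (adjusted p = 0.226), lysosome and autophagy genes 11 and 8 of 26 (12 and 8 adjusted over the list alone; adjusted p = 0.307) and cytoskeleton genes 12 and 9 of 28 (adjusted p = 0.668). Glycolysis genes had 3 higher and 9 lower of 19 (4 and 9 adjusted over the list alone; adjusted p = 0.207) and were called lower without resistant 1 (-0.26, adjusted p = 0.0105) and with DESeq2 (adjusted p = 0.0391). Among lineage lists, lung lineage genes had 6 higher and 2 lower of 12 (6 and 3 adjusted over the list alone; adjusted p = 0.177), neuroendocrine genes 1 and 3 of 6 (adjusted p = 0.613) and stem cell and drug-tolerance genes 5 and 6 of 15 (adjusted p = 0.921). Markers of other cell types were not called: fibroblast markers had 5 higher and 2 lower of 9 (adjusted p = 0.189, called higher with DESeq2 at 2.40e-09), immune markers 4 and 3 of 11 (adjusted p = 0.783) and endothelial markers 2 and 2 of 9 (adjusted p = 0.613). Nuclear-retained RNAs had 1 higher and 3 lower of 7 (adjusted p = 0.315). Ribosomal protein genes had 2 higher and 6 lower of 30 (median -0.03, adjusted p = 0.446) and were called lower without resistant 1 (-0.10, adjusted p = 0.00493) and with median centring (-0.16, adjusted p = 0.0312). For 5 lists, Wnt, Notch, drug-metabolising, stem cell and cytoskeleton genes, the median, the mean and the test differed in sign. Of the 22 called lists, 6 higher and 16 lower, the MAPK output and G2/M lists kept the call with an estimated correlation. fry called 31 lists in a direction and all 40 for change in either direction. For lists where no separate count is given, counts adjusted over the list alone were the same.

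Neighbouring genes on several chromosome arms moved together in the test with the preset correlation. Of 490 windows, 55 were called lower and 16 higher, and 0 were called with an estimated correlation, where the smallest value was adjusted p = 0.227 with an estimated correlation. On chromosome 2, a run from 0.218 to 54.3 Mb had a median log2 fold change of -0.46, with 83.4% of its expressed genes below 0; it holds EPCAM, PXDN and RRM2. Chromosome 5 was lower in 6 runs, the longest from 56.9 to 115.5 Mb (median -0.35) and the strongest from 127.7 to 141.0 Mb (median -0.48), which holds HBEGF. On chromosome 10, 86.7 to 133.6 Mb had a median of -0.50 and holds MKI67. On chromosome 17, 28.4 to 45.2 Mb (median -0.40) and 47.8 to 76.6 Mb (median -0.57) were lower; ERBB2 and TOP2A lie in the first and NGFR, which rose, in the second. Shorter lower runs lay on chromosome 7 from 2.53 to 17.3 Mb and on chromosome 11 from 125.9 to 135.0 Mb. Others lay on chromosome 1 from 155.7 to 156.7 Mb and on chromosome 7 from 30.5 to 38.4 Mb. Chromosome 17 was also lower from 81.4 to 82.2 Mb. A further lower run on chromosome 11, from 67.6 to 71.5 Mb (median -0.29), adjoined a higher run. Higher windows formed 4 runs on chromosome 7, the strongest over all tested genes from 110.7 to 127.4 Mb (median 0.53). Over expressed genes, the run from 76.6 to 91.3 Mb was stronger, with a median of 0.55 against 0.43. Chromosome 4 had 1 higher run, from 118.3 to 129.1 Mb (median 0.34). On chromosome 11, runs from 7.43 to 10.9 Mb (0.30), 71.5 to 74.0 Mb (0.38) and 113.3 to 120.2 Mb (0.37) were higher, and on chromosome 14 runs from 91.5 to 96.3 Mb (0.40) and 102.1 to 104.1 Mb (0.47). Chromosome 19 had 3 higher runs, with medians from 0.23 to 0.36. Expressed genes in lower windows had a median of -0.47, those in higher windows 0.32 and those outside called windows 0.04. Of the 5194 genes called lower, 23.7% lay in lower windows, which held 11.2% of tested genes. The windows were called from the fold changes of these same genes. The medians and shares of called windows and runs are therefore not separate evidence that neighbours moved together. With windows of 100 genes, 30 were called lower and 10 higher.

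**Figure D4:**
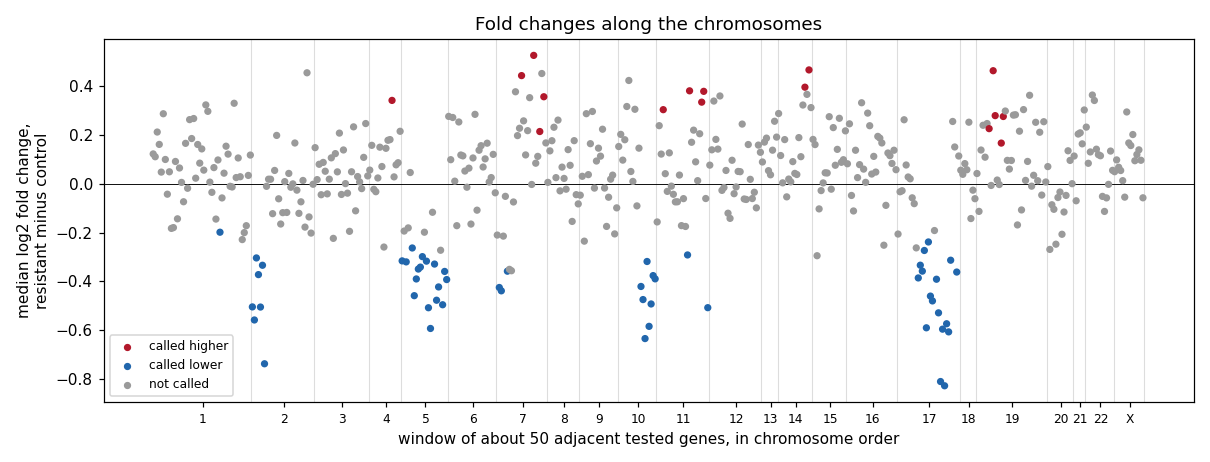
Median log2 fold change, resistant minus control, of each window of about 50 adjacent tested genes in order along chromosomes 1 to 22 and X; red windows were called higher, blue windows lower and grey windows were not called. Runs of blue windows stand on chromosomes 2, 5, 10 and 17.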

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

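The tests on recovered reads, the removal of GC and length trends the lists without genes of the lower windows, and the windows with an estimated correlation or fry were chosen after the data had been seen. The count of genes past the threshold ranged from 7573 (limma without trend) to 10423 (GC content and gene length removed), and for every setting 0 of the 10204 genes were called in the opposite direction. On recovered reads, edgeR called 9531 of 16630 genes (4731 higher, 4800 lower), limma-voom 9531 and DESeq2 8496. Leaving out 1 library gave 8746 to 10198 genes, 2906 to 3024 changed 2-fold, 20 to 23 gene lists and 60 to 70 windows. The number of called lists moved from 22 to 2 with an estimated inter-gene correlation (0 higher, 2 lower). That setting replaces the preset 0.01 with a value estimated for each list. Whether the estimated value itself ended the calls was not tested, so a lost call does not by itself show strong correlation between genes. fry called 11 lists higher; it tests each list alone and not against other genes. fry also turned the stem cell and drug-tolerance list, whose median is 0.336, to lower (adjusted p = 0.00989). The mean log2 fold change of that list was -0.05, on the same side as fry, and the cause was not tested further. Windows of 100 genes gave 40 calls, 10 higher and 30 lower, from fewer windows. With an estimated correlation the called windows moved from 71 to 0 (0 higher, 0 lower), while fry called 304 (176 higher, 128 lower). What ended the window calls was not tested either. Same-numbered libraries had correlations of deviations of -0.005, 0.007 and 0.063, so no shared deviation by number was evident. So few libraries cannot show that the numbers mark no shared day or batch. The replicate block gave 10175 genes. The alternatives planned for deposited counts alone (median-of-ratios factors or no scaling within edgeR) and for files with both units had no case here and were not run. limma without trend ended the calls of 26 named or added genes, among them ERBB2, FGFR1, IGF1R, NRAS and PIK3CA. With median centring the small rises of BID, BAD and SEL1L lost their calls. Depth limits genes near the floor of 3 reads per library.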

Other observations

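The tests on held-out genes of lower windows, on ribosomal protein genes, on the cell cycle genes and on COL1A2 were chosen after the results had been seen. The antigen presentation list was not called (adjusted p = 0.226), with members in both directions. The class II genes HLA-DRA and HLA-DPA1, with log2 fold changes of -3.21 and -3.28, and CD74, their invariant chain (-1.51), fell. HLA-B, a class I gene with near-identical relatives that can share reads, rose by 0.44. These genes were chosen after their values were seen, and a difference between the classes was not tested.

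With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05, and in each case 1 split, the real one, gave a result as large. The real split gave 10204 genes and 3334 changed 2-fold, against 0 and 0 at most in the other splits. It gave 71 windows, against at most 11 in the others. It gave 22 gene lists, against at most 15 in the others. Every other split mixes the groups unevenly, so part of the difference between the lines remains in it. Counts of genes, windows and lists from those splits therefore do not measure false calls.

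Neighbouring genes moved together along chromosomes, with 71 of 490 windows called at the preset correlation and 0 at an estimated correlation. After removing each library's trends on GC content and gene length, 100% of the called windows stayed called in the same direction, which argues against those trends as the whole cause. The most windows called in 100 shuffled gene orders was 0, which argues against chance order, and when lower windows were called from alternate genes, 80.3% of the 900 expressed genes held out of the call lay below 0, against 49.0% in windows not called, which argues against a few strongly changed genes. Different gene dosage in the resistant line could not be told apart from regional regulation: the 8 ribosomal protein genes in lower windows, called with all ribosomal protein genes held out, had a median that differed by -0.54 from that of 62 such genes outside called windows (two-sided permutation of whole windows, p = 4e-04), which either cause would give. DNA copy number was not analysed here, and a difference that existed before selection also stays open.

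Cell cycle genes fell together, with a median of -0.87 over 45 genes. The 37 genes outside the lower windows had a median of -0.81, which argues against position as the cause. Of 10000 random lists matched on mean expression, 0% had a median as low, which argues against a shift of all genes at this level or the scaling of the libraries. A candidate explanation is slower proliferation of the resistant cells at harvest, but growth was not analysed here. The resistant libraries carry the title Drug, and the labels do not state whether drug was present at harvest. Such exposure could not be separated from the resistant state.

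COL1A2 rose far more than other fibroblast genes. The upper 95% limit of the log2 fold change of COL1A1, its usual partner chain, was 0.19, at 4963 ± 300 in resistant and 4808 ± 428 in control libraries (SD, n = 3), which argues against fibroblasts among the resistant cells as the cause of a rise to 29275. Other members of the fibroblast list were called higher at low levels: LUM rose from 0 to 4.22 normalized read counts, COL3A1 from 2.74 to 11.4 and FBLN1 from 136 to 205, while COL6A3 fell from 28.3 to 2.21. PDGFRB, at 134 against 100, lost its call in 11 of 18 settings, and LUM with limma without trend and a pseudocount of 0.01. The other 49 genes of the COL1A2 window had a median of 0.25, which argues against a regional change of that size, and the mechanism was not tested.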
